A study of Mus musculus with 20 samples.

How the data were processed

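RNA was measured in 20 libraries of 3 cell populations (FAP, SMP and Misc) from mouse leg muscle under 2 conditions (DKO and WT), per the labels. Total RNA was isolated with a column kit after lysis in RLT buffer or TRIzol with chloroform, per the labels' protocols; how the populations were separated is not given in the sources used here. Libraries were read on an Illumina HiSeq 2500 in rapid run mode, with 100-base paired reads, 22 M reads per library on average and 2 to 4 biological replicates per population and condition, per the series design text. Reads were mapped to mm10 with RefSeq annotation by the aligner OSA, per the series design text, and DESeq2 is named without a version in the submitters' processing notes. The authors deposited raw counts per gene, which the file's name describes as exon counts; the counting tool and whether it used strand are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart. Whether each replicate came from a separate animal is likewise not given beyond the word biological, nor is any pooling of animals.

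The table held 24393 genes by Entrez identifier, of which 24312 matched the RefSeq table of GRCm38.p6, the assembly named mm10, used here for names and coordinates. Of the symbols, 25 were blank and 27 had turned into dates; these 52 were restored from their identifiers. No column was left out, and 5031 genes had no count in any library. Genes were kept when edgeR's filterByExpr passed them by group (minimum count 10, minimum total 15, smallest group 2), which left 14179. Counts were scaled by TMM, and CPM values printed in the text use these scaled totals. A quasi-likelihood model with robust dispersion was fitted in edgeR 4.0.16 (R 4.3.3) to all 6 groups at once, without a block. The tests were DKO against WT in each population, each pair of populations in DKO and in WT, and the difference of the DKO effect between each pair of populations. An adjusted p (Benjamini-Hochberg, over the genes of 1 comparison) below 0.05 was called, and each standard error is the absolute log2 fold change divided by the square root of F. Calls adjusted over the list alone use the same p-values adjusted within each gene list.

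Gene lists were written before the files were read, and 26 were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. They were fibrillar collagens, basement membrane, other collagens, small leucine-rich proteoglycans, elastic fibre and glycoproteins, matricellular proteins, matrix proteases and inhibitors, collagen processing and crosslinking, the TGF-beta pathway, and myofibroblast contractile genes. Cell type lists were satellite cell and myogenic, mature muscle fibre, fibro/adipogenic progenitor, tendon cell, adipocyte, immune, endothelial, pericyte and smooth muscle, Schwann cell and nerve sheath, and erythroid. The rest were cell cycle, immediate early and dissociation, chemokines and cytokines, complement, interferon response, and intermediate filament and nuclear envelope genes. Of 19 list calls over the 3 comparisons of DKO with WT, 1 held with the estimated correlation, matricellular proteins in FAP. Named genes followed a fixed rule: in each DKO comparison the 10 higher and 10 lower with the largest log2 change among those called, with mean CPM of at least 5 and groups that did not overlap, leaving out predicted genes. Between populations the rule took the 6 each way called alike in both genotypes, for each interaction 5 each way, and from each list up to 4 called members. Des, Syne1, Dmd, Utrn, Col1a1, Col1a2, Col3a1, Pdgfra, Ly6a, Pax7, Itga7, Xist, Ddx3y and the fibrillar collagens were kept in the table of named genes whatever their result, and not all of these are printed.

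Whether replicate numbers pair libraries was checked before any blocked result was read, by correlating deviations from the group means across genes. FAP and Misc libraries of the same number correlated at 0.18 to 0.34 in DKO and 0.18 to 0.23 in WT, over 4 pairs each, against −0.18 to 0.06 for other numbers, so the numbers were taken to pair FAP with Misc. The pairing comes from this check alone, as no label states it. Depth ranged from 5.83 to 17.73 M counts per library. On simulated counts with the same depths, the edgeR step (14003 genes tested) recovered 80% of 100 genes changed 2-fold and 94% of 100 changed 4-fold in FAP, calling 8 unchanged genes. It recovered 84% and 97% in Misc, calling 3, and 59% and 84% in SMP, calling 12. The simulation gave each gene the same spread in all groups and no pairing of libraries. It does not cover a group that varies more, as SMP DKO may. Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, only the compared groups in the fit, blocks by replicate number and by the letters of the table's columns, each replicate left out, and other thresholds. Counts thinned to the smallest library, DKO replicate 3 as the only DKO library, and both replicates numbered 1 left out were added after seeing the data. Where an alternative left 1 library in a group, that library was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.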

Results

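The series measured RNA in 3 cell populations taken from the quadriceps, tibialis anterior and gastrocnemius muscles of DKO and WT mice. Its title asks which cells of fibrotic muscle express extracellular matrix. The sample labels call the populations FAP, SMP and Misc, whereas the design text lists FAP, SMP and FB. No label ties Misc to FB, so the name Misc is used here. As background, FAP commonly stands for fibro/adipogenic progenitors, the mesenchymal cells between muscle fibres. SMP commonly stands for skeletal muscle progenitors, the stem cells that repair fibres. The labels do not say which genes DKO stands for. As an assumption from background, DKO is read here as loss of desmin (Des), an intermediate filament protein of muscle. The same assumption includes loss of nesprin 1 (Syne1), which ties nuclei to the cytoskeleton. There were 20 libraries: 4 each of FAP DKO, FAP WT, Misc DKO and Misc WT, and 2 each of SMP DKO and SMP WT. Library totals were 6739010 to 11039053 counts in FAP DKO and 10464761 to 13042515 in FAP WT. They were 8360658 to 8492813 in Misc DKO and 9566333 to 17730111 in Misc WT. In SMP they were 6124928 and 5826000 in DKO and 10659399 and 9669174 in WT, so SMP DKO was the shallowest group. Each fold change is a log2 value ± its standard error, and each abundance is in CPM (counts per 1e6 of TMM-scaled library total), given as mean ± SD where it is a group's. Each adjusted p for a gene is edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14179 genes. The n is 4 against 4 libraries for FAP and Misc, and 2 wherever SMP is a group. For gene lists, counts of higher and lower members come first over all genes and then, in the same order, adjusted over the list alone.

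Cell population separated the libraries most. The first principal component held 45.7% of the variance and put the SMP libraries at 100.9 to 131.2, with no FAP or Misc library above 2.3. The second held 26.7% and put FAP at 40.6 to 49.5 and Misc at −66.3 to −42. Genotype followed the third component (7.4%), with WT libraries of all populations at 21.1 to 29.8 and DKO libraries at −37.7 to −13.2. On the fourth (4.1%), SMP DKO replicate 2 lay apart at −61. Across genes, which are not independent replicates, Pearson's r between libraries of a group was 0.977 to 0.99 in FAP and Misc. It was 0.975 in SMP WT and 0.95 in SMP DKO.

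**Figure D1:**
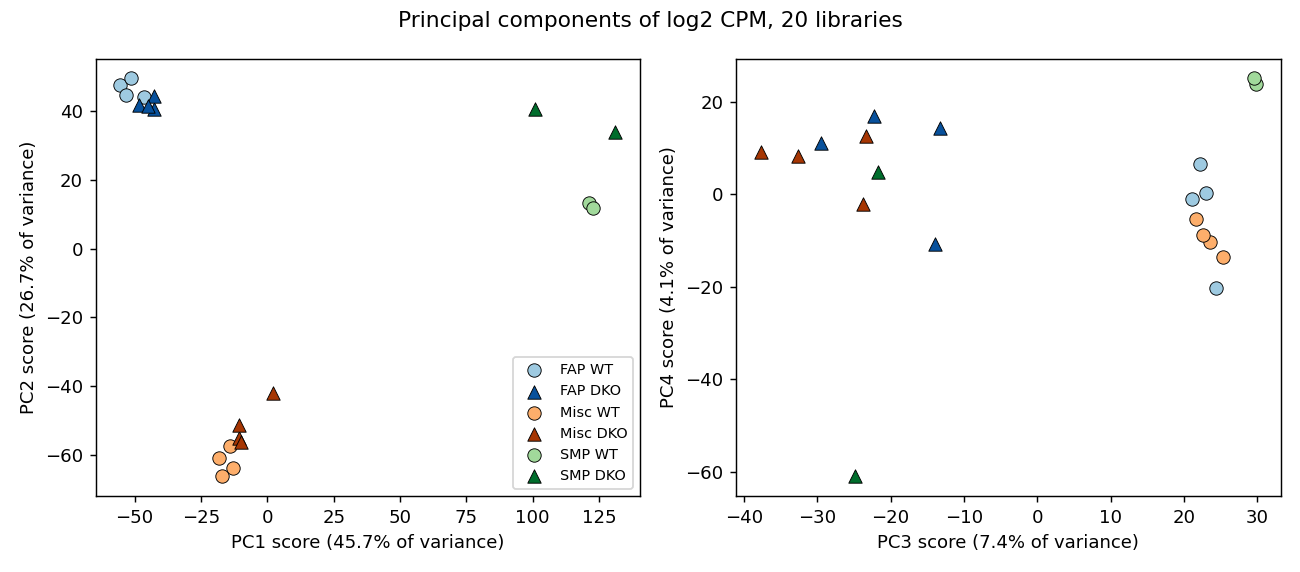
Principal component scores of the 20 libraries (axes in score units, with the percent of variance), coloured by group. Populations part on components 1 and 2, DKO (−37.7 to −13.2) and WT (21.1 to 29.8) on component 3, and SMP DKO replicate 2 (−61) stands alone on component 4.

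Des was lower in DKO in all 3 populations, and Syne1 in Misc and SMP, though not without overlap. Des (Entrez 13346, chromosome 1, 75360292 to 75368579 in mm10) was at 5.04, 5.33, 4.36 and 3.43 CPM in FAP DKO against 14.2, 18.3, 16.5 and 14.3 in FAP WT. Its fold change there was −1.81 ± 0.18, adjusted p = 2.7e-07. In Misc it was at 1.37, 2.27, 1.56 and 1.42 CPM in DKO against 4.66, 3.94, 4.74 and 2.16 in WT (−1.25 ± 0.25, adjusted p = 0.00094), so WT replicate 4 lay below DKO replicate 2. SMP held the most Des, at 75.4 and 54.2 CPM in DKO against 171 and 184 in WT (−1.45 ± 0.19, adjusted p = 1.6e-05). Syne1 (Entrez 64009, chromosome 10, 5020192 to 5550692) was at 45.4, 37.8, 42.7 and 55.3 CPM in FAP DKO against 59.8, 55.8, 52.7 and 57.1 in FAP WT. That difference did not pass (−0.31 ± 0.12, adjusted p = 0.11). Syne1 fell in Misc from 129.8, 91.8, 117 and 85.5 CPM to 67.1, 62.1, 59.2 and 75.5 (−0.69 ± 0.12, adjusted p = 0.00028). In SMP it fell from 79.5 and 69.2 CPM to 37.0 and 35.9 (−1.03 ± 0.18, adjusted p = 0.00032). Counts per whole gene cannot show a deleted part separately, and which genes or parts were deleted is not given in the sources used here. Dystrophin (Dmd), which anchors the same cytoskeleton at the membrane, did not pass in FAP (−0.04 ± 0.12) or Misc (0.15 ± 0.13) and fell in SMP (−0.93 ± 0.16, adjusted p = 0.00029). The muscle integrin Itga7 did not pass in FAP (0.38 ± 0.24), Misc (0.52 ± 0.25) or SMP (0.19 ± 0.25). Utrophin (Utrn), related to dystrophin, fell in Misc (−0.43 ± 0.09, adjusted p = 0.0013). Its falls in FAP (−0.31 ± 0.09, adjusted p = 0.028) and SMP (−0.51 ± 0.13, adjusted p = 0.0062) were lost with single libraries left out, in FAP DKO replicate 2 (0.1) or 3 (0.086) or WT replicate 1 (0.054), 3 (0.062) or 4 (0.1), and in SMP DKO replicate 2 (0.057) or WT replicate 1 (0.066). The SMP call was also lost with only the SMP groups in the fit (0.066).

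**Figure D2:**
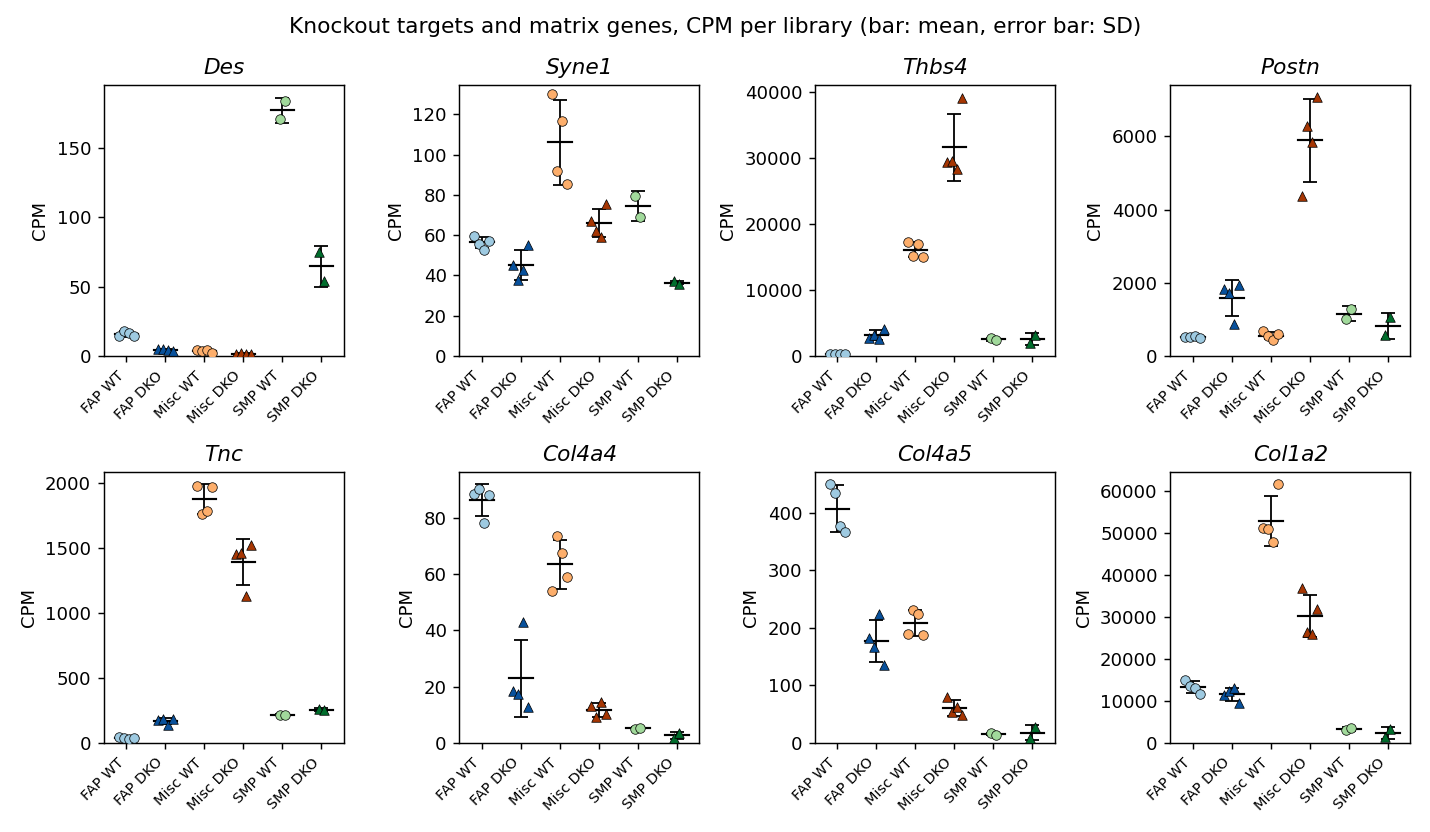
CPM of Des, Syne1, Thbs4, Postn, Tnc, Col4a4, Col4a5 and Col1a2 in each library (points; bars, group mean ± SD). Thbs4 averaged 3163 CPM in FAP DKO against 330 in FAP WT, and Postn 5902 in Misc DKO against 560.5 in Misc WT.

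In FAP, a set of matricellular and secreted matrix genes was higher in DKO, and the main fibrillar collagens did not pass. Thbs4 (thrombospondin 4, chromosome 13, 92751586 to 92794818), an adhesion protein of tendon and muscle matrix, rose from 330 ± 44.9 to 3163 ± 737 CPM (3.26 ± 0.18, adjusted p = 2.7e-11). Tenascin C (Tnc), deposited in injured tissue, rose from 38.6 ± 4.50 to 172 ± 23.6 CPM (2.16 ± 0.12, adjusted p = 2.7e-11). Periostin (Postn), which binds collagen, rose from 514 ± 19.8 to 1595 ± 488 CPM (1.63 ± 0.23, adjusted p = 0.00011). The protease inhibitor Timp1 (2.01 ± 0.12, adjusted p = 6e-11) and the short-chain collagen Col8a1 (2.24 ± 0.14, adjusted p = 1.1e-10) rose as well. So did the matrix protein Cilp (2.04 ± 0.18, adjusted p = 9.1e-08) and Ltbp2, which binds elastic fibres (2.31 ± 0.28, adjusted p = 4e-05). Col1a1 stood at 7797 ± 1122 CPM in DKO and 8910 ± 1019 in WT and did not pass (−0.19 ± 0.20, adjusted p = 0.6). Nor did Col1a2 (−0.20 ± 0.19, adjusted p = 0.56) or Col3a1 (−0.42 ± 0.16, adjusted p = 0.094). The naming rule also picked AI506816 (chromosome 5, 23692261 to 23712667, 5.49 ± 0.47) and the protease-activated receptor F2rl1 (3.08 ± 0.23) among the higher genes. Others it picked were the kinesin Kif1a (2.32 ± 0.24), the tachykinin gene Tac1 (2.26 ± 0.38) and the ATP receptor P2rx7 (2.19 ± 0.17). Contactin 1 (Cntn1), a cell adhesion gene, fell (−2.67 ± 0.46, adjusted p = 0.0013), as did neurexin 2 (Nrxn2, −1.91 ± 0.26). The kinase Prkg2 (−2.00 ± 0.21), the potassium channel Kcna2 (−1.67 ± 0.23) and the growth factor Bmp7 (−1.65 ± 0.27) fell too. Of 14179 genes, 791 were higher and 729 lower in DKO, 368 of the 1520 by at least 2-fold. Without FAP DKO replicate 2, the shallowest FAP library, 932 passed, and without FAP WT replicate 1, 997.

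Matricellular genes as a list rose in FAP, with 7 of 17 members higher, 0 lower and 10 not passing (8 and 1 adjusted over the list alone). Camera gave adjusted p = 5.7e-14, and adjusted p = 0.031 with an estimated correlation. Wisp1, a CCN family gene, was a member besides Thbs4, Tnc and Postn (1.57 ± 0.16). The tendon cell list, which shares Thbs4 and Comp with it, had 3 higher and 0 lower of 13 (4 and 0 adjusted over the list alone, camera adjusted p = 2.1e-06, adjusted p = 0.44 with an estimated correlation). Without DKO replicate 3, 5 of the tendon genes passed. Basement membrane genes fell, with 0 higher and 6 lower of 23 (0 and 9 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.78 with an estimated correlation). Type IV collagen chains of specialised basement membranes led them, with Col4a4 falling from 86.3 ± 5.56 to 22.9 ± 13.6 CPM (−1.90 ± 0.27, adjusted p = 0.00024). Col4a3 (−1.38 ± 0.27), Col4a6 (−1.29 ± 0.23) and Col4a5 (−1.20 ± 0.23) fell with it. Fibrillar collagens had 1 higher and 1 lower of 11 (1 and 1 adjusted over the list alone, camera adjusted p = 0.51), where Col27a1 (0.67 ± 0.15) rose and Col5a1 (−0.47 ± 0.11) fell. Other collagens had 4 higher and 1 lower of 20 (4 and 1 adjusted over the list alone, camera adjusted p = 0.041, adjusted p = 0.78 with an estimated correlation). Camera did not pass for them without DKO replicate 1 (0.089) or WT replicates 2 (0.071), 3 (0.06) or 4 (0.063). Proteases and their inhibitors had 6 higher and 3 lower of 23 (7 and 5 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.78 with an estimated correlation), and missed without WT replicate 3 (0.06) or 4 (0.075). Collagen-modifying enzymes had 3 higher and 2 lower of 23 (3 and 2 adjusted over the list alone, camera adjusted p = 0.32). Among them, the prolyl hydroxylase P4ha3 (1.91 ± 0.30) and the lysyl hydroxylase Plod2 (0.75 ± 0.13) rose. Small leucine-rich proteoglycans had 1 higher and 2 lower of 12 (2 and 2 adjusted over the list alone, camera adjusted p = 1), with biglycan higher (Bgn, 0.88 ± 0.14) and osteomodulin lower (Omd, −0.67 ± 0.13). Elastic fibre genes and glycoproteins had 6 higher and 5 lower of 27 (7 and 6 adjusted over the list alone, camera adjusted p = 0.84), and 6 members passed without DKO replicate 2. TGF-beta pathway genes had 4 higher and 2 lower of 28 (4 and 2 adjusted over the list alone, camera adjusted p = 0.1), including the response genes Id1 (0.96 ± 0.14) and Id2 (0.80 ± 0.09).

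Most cell state and cell type lists did not pass in FAP. Of 12 myofibroblast contractile genes, 0 were higher and 0 lower in edgeR (0 and 0 adjusted over the list alone, camera adjusted p = 1). Immediate early genes, which respond to tissue dissociation, had 1 higher and 7 lower of 18 (4 and 9 adjusted over the list alone, camera adjusted p = 0.041, adjusted p = 0.8 with an estimated correlation). Fosb (−0.70 ± 0.14), Btg2 (−0.67 ± 0.12) and Fos (−0.57 ± 0.11) were among those lower. The list did not pass without DKO replicates 1 (0.2) or 4 (0.08) or WT replicates 3 (0.06) or 4 (0.063). Its members passing numbered 4 without WT replicate 1 and 5 without DKO replicate 2 or 4. Endothelial genes, of a cell type other than FAP, had 0 higher and 1 lower of 14 (0 and 1 adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.8 with an estimated correlation), with Tek lower (−1.01 ± 0.13). This list did not pass without WT replicate 1 (0.22) or DKO replicates 3 (0.063) or 4 (0.093), and its marker Cdh5 was highest among FAP libraries in the replicates 1, at 29.1 CPM in WT and 14.5 in DKO against 2.45 to 10.6 in the others.

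In Misc, periostin and other matrix genes were higher in DKO, and the type I collagen genes were lower. Postn (chromosome 3, 54359267 to 54391041) rose from 560.5 ± 104 to 5902 ± 1134 CPM (3.40 ± 0.24, adjusted p = 2.3e-08). Asporin (Aspn), which binds collagen and TGF-beta, rose from 265 ± 49.3 to 1924 ± 358 CPM (2.86 ± 0.22, adjusted p = 4.9e-08). Fibronectin (Fn1) rose from 2660 ± 194 to 6365 ± 874 CPM (1.26 ± 0.14, adjusted p = 4.3e-07). The Wnt antagonist Frzb (4.31 ± 0.42, adjusted p = 1.3e-07) and the progenitor marker Pi16 (2.82 ± 0.50, adjusted p = 0.0012) rose as well. Col1a2 fell from 52910 ± 5976 to 30280 ± 5084 CPM (−0.81 ± 0.20, adjusted p = 0.005). Col1a1 fell (−0.68 ± 0.20, adjusted p = 0.018), but did not pass without DKO replicate 2 (0.069), DKO replicate 3 (0.06) or WT replicate 4 (0.06). AI506816 (4.39 ± 0.41), Rgs4 (3.79 ± 0.30), F2rl1 (3.77 ± 0.25) and Ltbp2 (2.46 ± 0.23) rose here as in FAP. Cntn1 (−3.70 ± 0.47, adjusted p = 4.4e-05) and Nrxn2 (−2.52 ± 0.25) fell here as in FAP. The collagenase Mmp13 (−2.98 ± 0.48, adjusted p = 0.00042) and cadherin 19 (Cdh19, −2.31 ± 0.20, adjusted p = 2.8e-08) fell too. The Notch targets Hey1 (2.00 ± 0.12) and Heyl (1.58 ± 0.16) rose in Misc, and in FAP by 1.16 ± 0.12 and 0.71 ± 0.17. Of the TGF-beta family, Tgfb1 rose from 25.7 ± 2.17 to 55.2 ± 4.98 CPM (1.11 ± 0.12, adjusted p = 2.4e-07). Tgfb2 (0.63 ± 0.11) and myostatin (Mstn, 1.92 ± 0.25) rose with it. Of 14179 genes, 1298 were higher and 1354 lower, 784 of the 2652 by at least 2-fold.

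Basement membrane genes fell in Misc too, with 3 higher and 11 lower of 23 (4 and 12 adjusted over the list alone, camera adjusted p = 0.00047, adjusted p = 0.68 with an estimated correlation). Fold changes in Misc fell with transcript length (Spearman's rho −0.17 across genes, which are not independent replicates), and how far this carries the list was not tested. Col4a4 fell from 63.5 ± 8.76 to 11.7 ± 2.38 CPM (−2.44 ± 0.29, adjusted p = 2e-05). Col4a3 (−1.97 ± 0.30), Col4a6 (−1.85 ± 0.27) and Col4a5 (−1.77 ± 0.23) were also lower. Fibrillar collagens went both ways, with 3 higher and 4 lower of 11 (3 and 5 adjusted over the list alone, camera adjusted p = 0.91). Col5a1 (0.43 ± 0.11), Col5a2 (0.52 ± 0.10) and Col27a1 (1.09 ± 0.16) were the higher ones. Matricellular genes also went both ways, with 3 higher and 6 lower of 17 (3 and 7 adjusted over the list alone, camera adjusted p = 0.91). Sparcl1 (1.66 ± 0.16) and Thbs4 (16120 ± 1165 to 31590 ± 5039 CPM, 0.97 ± 0.17) rose with Postn, while the CCN genes Wisp2 (−1.44 ± 0.24) and Nov (−1.20 ± 0.28) fell. The other matrix lists did not pass camera. Other collagens had 2 higher and 5 lower of 20 (3 and 5 adjusted over the list alone) and proteoglycans 1 higher and 4 lower of 12 (2 and 4 adjusted over the list alone). Elastic fibre genes had 7 higher and 7 lower of 27 (9 and 8 adjusted over the list alone) and collagen-modifying enzymes 5 higher and 7 lower of 23 (5 and 7 adjusted over the list alone). TGF-beta genes had 7 higher and 5 lower of 28 (8 and 5 adjusted over the list alone). Proteases and inhibitors had 6 higher and 6 lower of 23 (6 and 7 adjusted over the list alone), and 7 members passed without DKO replicate 4. The tendon cell list, which shares Kera, Fmod and Chad with the proteoglycans, had 3 higher and 4 lower of 13 (3 and 4 adjusted over the list alone, camera adjusted p = 0.42).

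Cell cycle genes rose in Misc, with 8 higher and 0 lower of 22 (9 and 0 adjusted over the list alone, camera adjusted p = 9.4e-05, adjusted p = 0.68 with an estimated correlation), and 5 passed without WT replicate 1. Myogenic genes, among them Hey1 and Heyl, had 5 higher and 1 lower of 22 (5 and 1 adjusted over the list alone, camera adjusted p = 0.00076, adjusted p = 0.68 with an estimated correlation). Muscle fibre genes had 6 higher and 0 lower of 20 (7 and 0 adjusted over the list alone, camera adjusted p = 0.0057, adjusted p = 0.82 with an estimated correlation). Acta1, an actin close in coding sequence to other actins, was one of the higher fibre genes (1.28 ± 0.28, adjusted p = 0.0041). Genes of pericytes had 0 higher and 3 lower of 11 (0 and 3 adjusted over the list alone, camera adjusted p = 0.0027, adjusted p = 0.68 with an estimated correlation), with Cspg4 lower (−1.26 ± 0.12). Genes of Schwann cells had 0 higher and 2 lower of 13 (0 and 2 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.68 with an estimated correlation), and 1 passed without WT replicate 1 or 3 or DKO replicate 2 or 3. Immediate early genes had 2 higher and 7 lower of 18 (3 and 8 adjusted over the list alone, camera adjusted p = 0.0091, adjusted p = 0.84 with an estimated correlation). Fosb (−1.24 ± 0.14) and Btg2 (−1.12 ± 0.12) fell. The heat shock genes Hspa1a (0.76 ± 0.14) and Hspa1b (0.80 ± 0.14) rose, and since they are near-identical the counting could split reads between them. Fibro/adipogenic progenitor genes had 1 higher and 5 lower of 15 (3 and 6 adjusted over the list alone, camera adjusted p = 0.055), and camera gave 0.049 without DKO replicate 3. The remaining lists did not pass camera. Intermediate filament and nuclear envelope genes had 4 higher and 6 lower of 16 (4 and 6 adjusted over the list alone) and myofibroblast genes 2 higher and 2 lower of 12 (2 and 2 adjusted over the list alone). Complement genes had 1 higher and 1 lower of 12 (1 and 1 adjusted over the list alone), and endothelial genes 0 higher and 1 lower of 14 (0 and 1 adjusted over the list alone). Chemokines and cytokines had 0 higher and 3 lower of 19 (2 and 4 adjusted over the list alone), with 5 passing without DKO replicate 1. Interferon response genes had 0 higher and 1 lower of 16 (0 and 1 adjusted over the list alone), with 2 passing without WT replicate 1. Adipocyte genes had 1 higher and 2 lower of 8 (1 and 3 adjusted over the list alone), with 1 passing without WT replicate 1. Immune genes had 0 higher and 0 lower of 16 (0 and 0 adjusted over the list alone, camera adjusted p = 0.2).

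**Figure D3:**
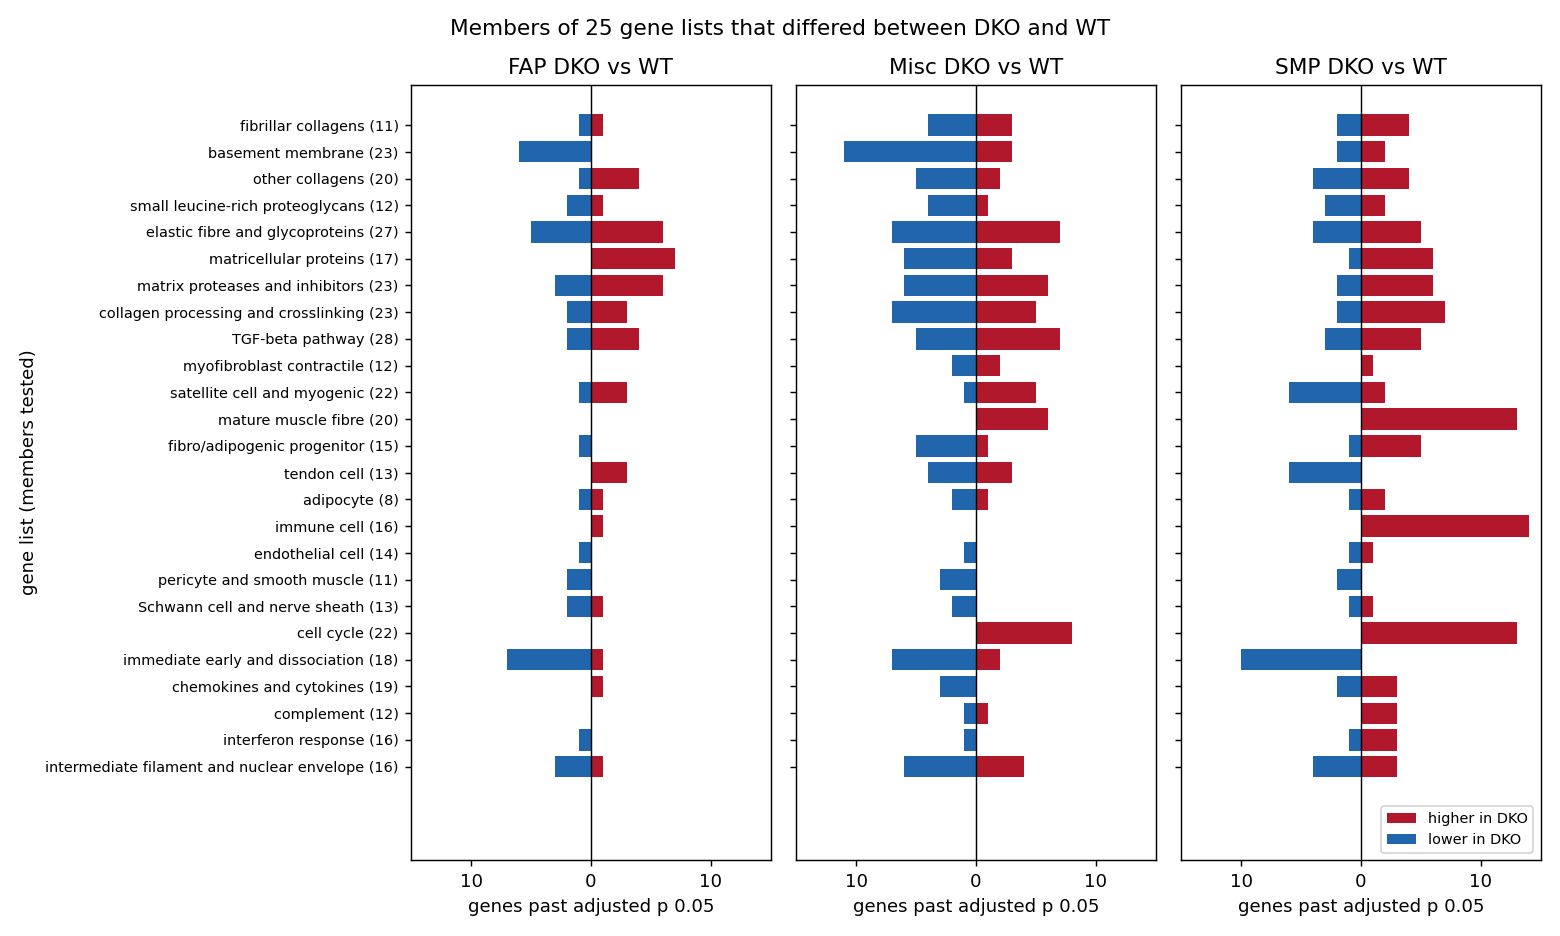
Number of members of 25 gene lists that were higher (red, right) or lower (blue, left) in DKO than in WT in each population at an adjusted p below 0.05. Matricellular genes had 7 members higher in FAP, basement membrane genes 11 lower in Misc, and muscle fibre genes 13 higher in SMP.

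In SMP, genes of muscle fibres were higher in DKO and immediate early genes lower, on 2 libraries per group. Both list calls were lost with an estimated correlation (adjusted p = 0.3 and adjusted p = 0.3 by camera). Mylpf (chromosome 7, 127208848 to 127214288), a myosin light chain of fast fibres, was at 11.3 and 27.3 CPM in DKO against 1.22 and 0.877 in WT (4.18 ± 0.47, adjusted p = 2e-06). The fibre genes Tnni2 (3.90 ± 0.56, adjusted p = 5.7e-05) and Myl1 (3.55 ± 0.51, adjusted p = 8.1e-05) rose with it. Ckm, the creatine kinase of fibres, rose too (3.68 ± 0.57, adjusted p = 0.00017), by 2.24 without DKO replicate 2. The immediate early gene Fos fell from 3880 ± 153 to 1301 ± 239 CPM (−1.58 ± 0.16, adjusted p = 6.3e-07). Egr1 (−1.44 ± 0.16), Btg2 (−1.74 ± 0.17) and Fosb (−1.40 ± 0.19) fell with it. Among matrix genes, Col8a1 rose from 43.3 ± 0.227 to 161 ± 55.2 CPM (1.89 ± 0.20, adjusted p = 1.1e-06). Col27a1 (1.64 ± 0.23), Col5a3 (0.92 ± 0.19), Smoc1 (1.76 ± 0.33), Timp3 (0.92 ± 0.15) and Tgfb2 (1.24 ± 0.15) rose as well. The fibro/adipogenic progenitor gene Ly6a was at 3.43 CPM in DKO replicate 1 and 78.8 in DKO replicate 2. Other matrix genes, such as Col14a1 and Lum, changed direction without replicate 2. How much of the matrix rises comes from cells of another type in that library was not measured. Col11a1 (−1.52 ± 0.22), Col24a1 (−1.43 ± 0.27), osteomodulin (Omd, −1.31 ± 0.23) and the TGF-beta receptor Tgfbr3 (−1.23 ± 0.14) fell. The naming rule also picked the calcium channel genes Cacna2d4 (−3.88 ± 0.60) and Cacna1d (−2.82 ± 0.35) and the transporter Slc22a3 (−3.40 ± 0.44) among the lower genes. It picked Rgs4 as lower (−2.57 ± 0.37, adjusted p = 0.00015), a gene that rose in FAP (2.18 ± 0.33) and Misc (3.79 ± 0.30). The stem cell factor Pax7 was at 125 and 100.2 CPM in DKO against 262 and 270.5 in WT (−1.24 ± 0.34, adjusted p = 0.017). It did not pass without DKO replicate 2 (0.096) or WT replicates 1 (0.065) or 2 (0.066). The myogenic factor Myod1 was at 338 and 353 CPM in DKO against 132 and 140.3 in WT (1.35 ± 0.40, adjusted p = 0.025). It did not pass without DKO replicates 1 (0.063) or 2 (0.081) or WT replicates 1 (0.12) or 2 (0.095). Of 14179 genes, 1671 were higher and 1586 lower, 1199 of the 3257 by at least 2-fold. With only the SMP libraries in the fit, 924 passed (445 higher, 479 lower). Without SMP DKO replicate 2, 2219 passed (954 higher, 1265 lower), 1771 of them among the 3257. Without SMP DKO replicate 1, 2830 passed (1648 and 1182), and without SMP WT replicate 1, 1821. Both SMP DKO libraries held 0 CPM of the Y-linked gene Ddx3y against 168 and 140 in WT, so sex and genotype go together here. Fold changes fell with transcript length (Spearman's rho −0.24 across genes, which are not independent replicates), and how far this carries the SMP results was not tested.

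Muscle fibre genes as a list had 13 higher and 0 lower of 20 (14 and 1 adjusted over the list alone, camera adjusted p = 6.1e-10, adjusted p = 0.3 with an estimated correlation). Of these, 12 were higher without DKO replicate 2. Immediate early genes had 0 higher and 10 lower of 18 (1 and 11 adjusted over the list alone, camera adjusted p = 6.1e-10, adjusted p = 0.3 with an estimated correlation), and 6 passed without WT replicate 1. Cell cycle genes had 13 higher and 0 lower of 22 (15 and 0 adjusted over the list alone, camera adjusted p = 1e-06, adjusted p = 0.31 with an estimated correlation). Of these, 6 passed without DKO replicate 1 and 2 without WT replicate 1. Myogenic genes had 2 higher and 6 lower of 22 (2 and 8 adjusted over the list alone, camera adjusted p = 0.18), and 5 passed without WT replicate 1, WT replicate 2 or DKO replicate 2. For that list camera gave 0.036 without DKO replicate 1. Tendon cell genes had 0 higher and 6 lower of 13 (1 and 6 adjusted over the list alone, camera adjusted p = 0.0028, adjusted p = 0.84 with an estimated correlation), with Mkx lower (−1.75 ± 0.23). Camera gave 0.38 for them without DKO replicate 1. Fibrillar collagens had 4 higher and 2 lower of 11 (4 and 3 adjusted over the list alone, camera adjusted p = 0.92). The markers Cd74 and Pdgfra rose in one library. The immune gene Cd74 was at 3.43 and 274 CPM in DKO against 1.70 and 0.789 in WT (6.77 ± 1.85, adjusted p = 0.018), and its fold change was 1.43 without DKO replicate 2. The fibroblast gene Pdgfra was at 10.2 and 112 CPM in DKO against 9.32 and 10.4 in WT (2.62 ± 0.63, adjusted p = 0.0094), and its fold change was 0.03 without that library. Pericyte genes had 0 higher and 2 lower of 11 (0 and 2 adjusted over the list alone, camera adjusted p = 0.26), and without DKO replicate 2, 3 were lower and camera gave 0.013. Of them 2 were higher and 0 lower without DKO replicate 1, and 0 passed in edgeR without either WT replicate. Endothelial genes had 1 higher and 1 lower of 14 (1 and 1 adjusted over the list alone) and Schwann cell genes 1 higher and 1 lower of 13 (1 and 1 adjusted over the list alone), neither past camera. Without DKO replicate 1, 4 endothelial genes were higher and camera gave 0.00041; without either replicate 2 or WT replicate 1, 1 passed. Of the Schwann cell genes 1 or 0 passed with any SMP library left out. Immune genes had 14 higher and 0 lower of 16 (15 and 0 adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.84 with an estimated correlation). Without DKO replicate 2, 0 of them passed in edgeR and camera gave adjusted p = 0.19. Their median log2 ratio to the WT mean was 0.43 in DKO replicate 1 and 5.42 in DKO replicate 2. For muscle fibre genes it was 1.62 and 2.86. Fibro/adipogenic progenitor genes had 5 higher and 1 lower of 15 (7 and 1 adjusted over the list alone, camera adjusted p = 0.078), with 0 higher and 5 lower without DKO replicate 2. Without WT replicates 1 and 2 in turn, 2 and 3 of these passed. Without DKO replicate 1, 16 did, with 1 more gene tested; the list median was −0.6 in that library and 1.73 in replicate 2. The erythroid list kept 1 gene with enough counts, Alas2, which was higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.38).

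**Figure D4:**
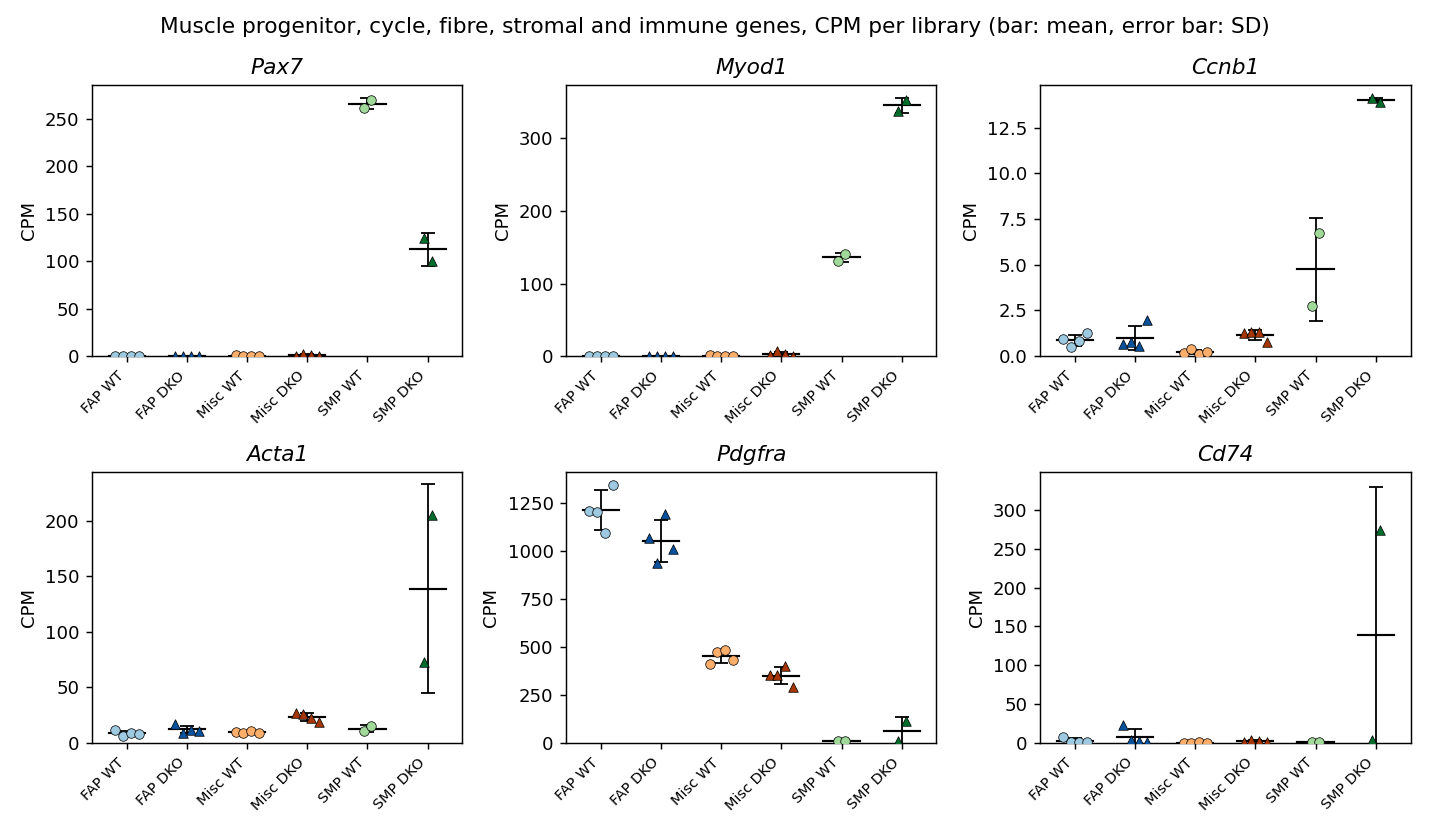
CPM of Pax7, Myod1, Ccnb1, Acta1, Pdgfra and Cd74 in each library (points; bars, group mean ± SD). In SMP DKO, replicate 2 held 274 CPM of Cd74 and 112 of Pdgfra, against 3.43 and 10.2 in replicate 1.

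Changes in FAP and Misc went largely the same way, a comparison the design raises because both populations make matrix. Of the genes past the threshold in both, 386 were higher in both (72.41 for independent lists of these sizes), 395 lower in both (69.61) and 33 opposite. Col4a3, Col4a4, Col4a5, Col4a6, Cntn1 and Nrxn2 were lower in both. Thbs4, Postn, Timp1, Cilp, Ltbp2, P4ha3, Hey1 and Heyl were higher in both. In Misc, P4ha3 rose by 1.57 ± 0.30, Timp1 by 1.48 ± 0.11 and Cilp by 1.16 ± 0.18. The interferon-induced gene Xaf1 fell in FAP (−1.13 ± 0.16), Misc (−1.37 ± 0.18) and SMP (−1.79 ± 0.25). It was the only member of the interferon response list called in Misc, so it does not stand for that list. Oas2, outside the list and at a mean of 1.43 CPM, rose in FAP (1.48), Misc (2.23) and SMP (2.37). Fold changes correlated at r = 0.48 across genes, which are not independent replicates. No library is shared, but same-numbered FAP and Misc libraries deviated together, and how much of the overlap comes from that was not measured.

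FAP and Misc differed in the matrix genes they expressed, in both genotypes. Tendon genes were higher in Misc, such as Thbs4 (FAP minus Misc −3.32 ± 0.18 in DKO, −5.61 ± 0.20 in WT). The tendon transcription factors Scx (−5.57 ± 0.21 in DKO, −6.71 ± 0.25 in WT) and Mkx (−6.08 ± 0.19 in DKO, −6.68 ± 0.18 in WT) were higher there too. So were the collagens Col22a1 (−6.47 ± 0.34 in DKO, −6.15 ± 0.36 in WT) and Col2a1 (−6.58 ± 0.52 in DKO, −7.49 ± 0.51 in WT). Col1a1 (−1.61 ± 0.20 in DKO, −2.10 ± 0.20 in WT) and Col1a2 (−1.39 ± 0.20 in DKO, −1.99 ± 0.20 in WT) were also higher in Misc. Col3a1, by contrast, was higher in FAP (1.12 ± 0.16 in DKO, 1.85 ± 0.16 in WT). FAP held more of the surface antigens Ly6a (6.43 ± 0.64 in DKO, 6.76 ± 0.63 in WT) and Ly6c1 (6.79 ± 0.64 in DKO, 6.65 ± 0.61 in WT), members of a family with similar sequences. The stromal marker Cd248 (4.70 ± 0.39 in DKO, 6.25 ± 0.42 in WT) and the protease Adamts16 (6.50 ± 0.51 in DKO, 7.28 ± 0.44 in WT) were higher in FAP as well. Complement factor B (Cfb, 4.32 ± 0.35 in DKO, 3.72 ± 0.34 in WT) and Il6 (2.00 ± 0.27 in DKO, 2.11 ± 0.27 in WT) were higher in FAP, with adjusted p of at most 2e-05. With FAP minus Misc taken as the direction, the tendon cell list had 0 higher and 12 lower of 13 (0 and 12 adjusted over the list alone, camera adjusted p = 3.4e-40, adjusted p = 0.0012 with an estimated correlation) in DKO. In WT it had 0 higher and 12 lower of 13 (0 and 12 adjusted over the list alone, camera adjusted p = 1.3e-40, adjusted p = 0.00068 with an estimated correlation). The matricellular list had 3 higher and 12 lower of 17 (3 and 13 adjusted over the list alone, camera adjusted p = 2.2e-14, adjusted p = 0.021 with an estimated correlation) in DKO. It had 2 higher and 12 lower of 17 (2 and 12 adjusted over the list alone, camera adjusted p = 4.6e-20, adjusted p = 0.004 with an estimated correlation) in WT. In all, 2269 genes were higher in FAP and 1944 higher in Misc in DKO, and 2740 and 2489 in WT. The basement membrane list of the WT comparison had 13 higher and 4 lower of 23 (13 and 4 adjusted over the list alone, camera adjusted p = 0.03, adjusted p = 0.64 with an estimated correlation). For it camera gave 0.15 with replicate number as a block and 0.057 without Misc WT replicate 4.

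Set against SMP, both populations held less of the myogenic genes and more Col1a1 and Col3a1. Pax7 was lower in FAP (−9.89 ± 0.56 in DKO and −10.02 ± 0.47 in WT) and in Misc (−6.50 ± 0.41 in DKO and −8.73 ± 0.42 in WT) than in SMP. Myod1 was lower in FAP (−11.51 ± 0.62 in DKO and −9.67 ± 0.60 in WT) and in Misc (−6.84 ± 0.43 in DKO and −8.11 ± 0.51 in WT). For FAP minus SMP in DKO, the satellite cell list had 0 higher and 22 lower of 22 (0 and 22 adjusted over the list alone, camera adjusted p = 9.6e-30, adjusted p = 0.01 with an estimated correlation). For Misc minus SMP in DKO it had 1 higher and 21 lower of 22 (1 and 21 adjusted over the list alone, camera adjusted p = 1.3e-20, adjusted p = 0.018 with an estimated correlation). Col1a1 was higher than in SMP in FAP (2.04 ± 0.27 in DKO and 1.84 ± 0.26 in WT) and in Misc (3.65 ± 0.29 in DKO and 3.93 ± 0.30 in WT). Col3a1 was likewise higher in FAP (3.01 ± 0.23 in DKO and 3.79 ± 0.24 in WT) and in Misc (1.89 ± 0.21 in DKO and 1.94 ± 0.21 in WT). The vesicle gene Sv2c was higher in FAP (5.52 ± 0.65 in DKO and 6.09 ± 0.60 in WT). The genes Faim2 (6.81 ± 0.68 in DKO and 7.93 ± 0.54 in WT), Cthrc1 (4.36 ± 0.40 in DKO and 5.02 ± 0.41 in WT) and Comp (4.06 ± 0.52 in DKO and 5.62 ± 0.57 in WT) were higher in Misc. For Misc minus SMP in DKO, the matricellular list had 16 higher and 0 lower of 17 (16 and 0 adjusted over the list alone, camera adjusted p = 3.9e-10, adjusted p = 0.018 with an estimated correlation). The collagen-modifying enzymes had 21 higher and 1 lower of 23 (21 and 1 adjusted over the list alone, camera adjusted p = 1.1e-11, adjusted p = 0.027 with an estimated correlation) there. For FAP minus SMP in DKO, the matricellular list had 11 higher and 4 lower of 17 (11 and 4 adjusted over the list alone, camera adjusted p = 0.15). List results against SMP in WT are not printed here. The DKO comparisons include SMP DKO replicate 2, which held 78.8 CPM of Ly6a against 3.43 in replicate 1. SMP WT held 8.11 and 6.93, so the DKO differences from SMP may partly reflect other cells in that library. Genes higher in FAP than in SMP numbered 4140 in DKO and 4407 in WT, and lower 4204 and 4431. Genes higher in Misc than in SMP numbered 4226 in DKO and 4341 in WT, and lower 4206 and 4250.

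The difference between DKO and WT itself differed between populations for some genes, as tested by the interaction term. Between FAP and Misc, 194 genes changed more upward in FAP and 202 more upward in Misc. With replicate number within genotype as a block 445 passed, and with a block by column letters 737 (411 and 326). Tnc (2.58 ± 0.17, adjusted p = 9e-10) and Thbs4 (2.29 ± 0.24, adjusted p = 3.2e-06) changed more upward in FAP, where their WT level was lower. This holds on the log2 scale. In CPM, Thbs4 rose by more in Misc than in FAP, and it was higher in Misc in both genotypes. Aspn changed more upward in Misc (−2.37 ± 0.30, adjusted p = 0.00011). Pi16 did too (−3.39 ± 0.68, adjusted p = 0.013), but not past the threshold with replicate number as a block (0.065). The matricellular list had 6 higher and 1 lower of 17 (9 and 2 adjusted over the list alone, camera adjusted p = 1.3e-14, adjusted p = 0.029 with an estimated correlation) toward FAP. Between FAP and SMP, 697 genes changed more upward in FAP and 768 in SMP, with Rgs4 toward FAP (4.75 ± 0.50, adjusted p = 1.6e-05). Their total of 1465 was 1022 without SMP DKO replicate 2 (662 toward FAP, 360 toward SMP), 1783 without replicate 1 (704 and 1079) and 777 without SMP WT replicate 1. Between Misc and SMP, 653 changed more upward in Misc and 615 in SMP, but 585 and 653 with DESeq2 size factors and 686 and 857 with its Wald test. Postn (3.89 ± 0.40, adjusted p = 5.4e-06) and Col22a1 (3.55 ± 0.47, adjusted p = 0.00016) were among those toward Misc. Their total of 1268 was 800 with only the groups compared in the fit, 933 without SMP DKO replicate 2 (598 toward Misc, 335 toward SMP) and 782 without SMP WT replicate 1.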

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

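Of the tests in this part, those of depth, of other cell types in SMP DKO replicate 2, and of other splits of the libraries were chosen only after the result was seen, as was the fit with both replicates numbered 1 left out.

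In groups of 4 libraries, 18 of 179 sets of values had a library far from the other 3 (Dixon's gap test at its 95% critical value for 4 values). About 1 in 20 would do so for independent normal values. The genes here share libraries, and some are sex-linked or near 0 CPM, so 18 is not shown to exceed chance. FAP DKO replicate 2 was shallow, at 6.74 M counts against 10.66 to 11.04 M. FAP DKO replicate 1 held more endothelial Cdh5 (14.5 CPM against 2.45 to 3.58) and immune Ptprc (1.77 against 0 to 0.157), and FAP WT replicate 1 more Ptprc (1.81 against 0 to 0.0952). In FAP DKO, replicate 3 stood apart for Col4a3 (50 CPM against 21.4 to 25.8) and Fn1 (5620 against 6820 to 6920), and replicate 4 for Sparcl1 (3380 against 2590 to 2700). Misc DKO replicate 4 stood apart for Thbs4 (39100 CPM against 28400 to 29600), Col4a3 (7.77 against 13.5 to 13.8) and Tgfb1 (62.5 against 51.6 to 53.5). Misc WT replicate 4 did so for Col1a1 (46000 against 35100 to 35800) and Col3a1 (6380 against 7910 to 8170), replicate 1 for Utrn (217 against 193 to 195), and replicate 2 for Fosb (2690 against 2420 to 2450).

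Sex-linked genes set DKO replicate 3 apart from the other DKO libraries. The Y-linked gene Ddx3y was at 144 CPM in FAP DKO replicate 3 against 0 to 0.313 in the others, and at 89.6 in Misc DKO replicate 3 against 0 to 0.129; Xist was at 0.36 there against 374 to 447. Every WT library held both Xist and Ddx3y, with FAP WT replicate 4 at 95.7 CPM of Ddx3y against 119 to 124. WT libraries could be pools of animals of both sexes and DKO libraries not, though no source used here states it. In that case the WT SDs are not those between animals. The p-values of DKO against WT would then rest on a spread that mixes pools with single animals. Sex as the whole source of the DKO changes in FAP and Misc is argued against: of autosomal genes called from DKO replicates 1, 2 and 4, 96.1% kept their direction in replicate 3 (1275 of 1317 in FAP, 2140 of 2235 in Misc). With separate WT libraries for calling and for checking, 95.6% of 701 genes in FAP and 88.7% of 1545 in Misc kept it. In SMP sex stays open, since it goes with the genotype there: Ddx3y was at 0 CPM in both DKO libraries and at 168 and 140 in WT. The lower depth of DKO libraries is argued against too, since 78.7% of calls over both populations remained, in the same direction, once every library was thinned to the smallest total. The genotype itself stays open and was not tested here. So does any difference that goes with it in the housing, age or strain of the animals, or in the handling of the samples. The table's columns were lettered B to P for DKO and BB to PP for WT, so handling may go with genotype.

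By the test of the difference itself, 396 genes changed differently with DKO in FAP and in Misc. The log2 difference (FAP minus Misc) was 2.71 for Ddah1, 2.58 for Tnc, 2.55 for C1qtnf3, 2.41 for Crtac1 and 2.29 for Thbs4. It was −3.39 for Pi16, −3.06 for Islr2, −2.76 for Fmo2, −2.37 for Aspn and −2.28 for Kcnab1. With both replicates numbered 1 left out, the adjusted p of edgeR's quasi-likelihood test was 0.11 for Pi16 and 0.054 for Crtac1. Of the 35 splits that keep FAP and Misc libraries of a number together, 1, the real one, gave as many genes (highest other 0). Every other split mixes DKO and WT libraries in its groups, so the DKO effect itself widens the spread there. Splits that keep the pairs thus cannot test whether the DKO effect differs between FAP and Misc. Of 99 drawn splits that part such pairs, 1 gave as many, 1212; it set all 4 Misc DKO libraries against Misc WT but 3 WT libraries and 1 DKO library against the other FAP libraries, and another with the 4 Misc DKO libraries on one side called 269, so these point to a structure of the samples, the genotype in Misc. For FAP, 1 of 35 splits of DKO and WT libraries, the real one, gave as many as its 1520 genes (highest other 1). For Misc it was also 1 of 35 (2652 against 0). Here too every other split mixes DKO and WT libraries, so the low counts of those splits are no added support. A share of 1 of 35 is the lowest possible here, so chance is unlikely for these counts but not excluded. The splits cannot tell the genotype from anything that goes with it, such as the column letters. For FAP against Misc, the 8 splits that part all 4 numbered pairs are too few for a share under 0.05 (1 of 8 gave as many, with 4213 genes in DKO and 5229 in WT and a highest other of 0 in both); the other 27 leave pairs together and called at most 111 in DKO and 0 in WT.

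The DKO effect also differed between FAP and SMP for 1465 genes and between Misc and SMP for 1268. FAP minus SMP was 4.75 for Rgs4, 3.36 for Dclk3, 3.28 for Rhoh (2.64, adjusted p = 0.1 by edgeR's quasi-likelihood test, without FAP DKO replicate 1), 3.25 for Kif1a and 3.24 for Thbs4. On the other side it was −6.27 for Wnt10b and −5.67 for 1700019D03Rik, both at 0 counts in SMP WT so that these values depend on the prior count, −4.61 for Cmah, −4.49 for Il1r2 and −4.37 for Pik3r5. Misc minus SMP was 6.36 for Rgs4, 5.22 for Serinc2, 4.31 for Mgam, 3.89 for Postn and 3.55 for Col22a1. It was −4.81 for Ces1d, −4.65 for C3, −4.43 for Kcp, −4.38 for Ifi205 and −4.37 for Dpep1. Without SMP DKO replicate 2, these became −0.73 for Wnt10b, −0.31 for 1700019D03Rik, 2.98 for Cmah, −1.73 for Il1r2, −2.68 for Ces1d, −0.08 for C3, −2.70 for Kcp, −0.92 for Ifi205 and 0.72 for Dpep1, none past the threshold. Leaving out SMP WT replicate 1 also ended the calls of Wnt10b (adjusted p by edgeR's quasi-likelihood test 0.15), 1700019D03Rik (0.11), Cmah (0.057), Il1r2 (0.057), Ces1d (0.071), C3 (0.077), Ifi205 (0.095) and Dpep1 (0.088). Leaving out SMP WT replicate 2 ended those of Wnt10b (0.12), 1700019D03Rik (0.091), Cmah (0.097), Il1r2 (0.11), C3 (0.11), Ifi205 (0.086) and Dpep1 (0.12), and Wnt10b was also at 0.052 to 0.06 without FAP WT replicate 1 or 4 or FAP DKO replicate 2, 3 or 4.

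Immune and muscle fibre genes were higher in SMP DKO than in SMP WT, list calls lost with an estimated correlation (camera adjusted p = 0.84 and 0.3). For the immune genes, cells of another type in SMP DKO replicate 2 are a candidate source: without that library 0 of the immune list passed, and the list's median log2 ratio to WT was 0.43 in replicate 1 against 5.42 in replicate 2. For the muscle fibre genes, such cells in that library are argued against as the whole source, since 12 of the 13 called with every library stayed higher without it. Differentiation of the DKO cells stays open for the fibre genes: of Myog, Mymk, Myh3 and Myh8, 2 (Myh3 and Myh8) had log2 ratios above 1 in both DKO libraries, and with 2 libraries per group this cannot be told apart from fibre RNA carried into both. Any sorting that would remove immune cells or fibres is not given in the sources used here.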

How the results depend on the processing

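The fits on thinned counts, with DKO replicate 3 as the only DKO library and with both replicates numbered 1 left out were chosen after seeing the data; all other alternatives were chosen before the data were examined. DESeq2's size factors left 1008 of the named genes' results on their side of the threshold and 2 weaker, its Wald test 986 and 5, no filter 994 and 15 (1 stronger), the compared groups alone 907 and 80 (9 stronger), and thinning 997 and 13. Fitting only the groups compared moved the SMP DKO count from 3257 to 924 and the Misc to SMP interaction from 1268 to 800. It raised the FAP DKO count from 1520 to 2214 and the FAP to Misc interaction from 396 to 590. The cause was not tested, nor was whether the spread shared over all groups is too small for SMP. Leaving out each replicate moved the counts over these ranges: FAP DKO 932 to 1696, Misc DKO 2002 to 2560, SMP DKO 1821 to 2830, FAP against Misc 3707 to 4155 in DKO and 4577 to 4905 in WT, FAP against SMP 6630 to 8197 and 7653 to 8551, and Misc against SMP 6889 to 8427 and 7262 to 8439. The interaction counts ranged from 279 to 379 (FAP and Misc), 777 to 1783 (FAP and SMP) and 782 to 1583 (Misc and SMP). Over all these alternatives, which direction held more genes turned in at least 1 fit for each comparison except FAP DKO against WT and FAP against Misc in DKO. Over the fits with a replicate left out 6472 results of named genes kept their side, 363 were weaker, 10 stronger and 13 reversed. The reversed ones were, without SMP DKO replicate 2, in SMP DKO Col14a1 (range −1.01 to 4.36), Lum (−0.21 to 2.74), Mfap5 (−0.29 to 2.27), Fap (−0.05 to 1.80), Ly6a (−1.14 to 3.37) and C3 (−0.93 to 4.61), then Cd74, FAP vs SMP in DKO (−6.18 to 1.15), H2-Aa, FAP vs SMP in DKO (−6.09 to 1.52), Laptm5, FAP vs SMP in DKO (−6.72 to 0.68), H2-Ab1, FAP vs SMP in DKO (−5.47 to 0.60), Ly6a, Misc vs SMP in DKO (−3.79 to 0.72), and the interaction results Cmah, DKO effect FAP vs SMP (−8.07 to 2.98) and Dpep1, DKO effect Misc vs SMP (−5.36 to 0.72); the cause was not tested. Of the lists in SMP DKO, other collagens (6 members past the threshold in that fit against 8 with every library, range 5 to 8) and proteoglycans (5 against 5, range 2 to 7) reversed without SMP DKO replicate 1, and elastic fibre (11 against 9, range 4 to 14) and progenitor genes (5 against 6, range 2 to 16) without replicate 2; the cause was not tested. With DKO replicate 3 alone, 377 genes passed in FAP and 1002 in Misc, 179 alike in both (781 with all), as fewer libraries allow, and Xist reversed (−7.71 in FAP, −8.72 in Misc), as that library's own low Xist shows. With both replicates numbered 1 left out, 246 genes passed in the FAP to Misc interaction. Of 19 list calls 1 held with the estimated correlation, and over all comparisons 95 list results were weaker with it. At thresholds of 0.01 and 0.1, 360 and 1166 genes changed alike in FAP and Misc. Blocking by replicate number gave 4412 and 5448 genes for FAP against Misc and 445 for their interaction; it ended the calls of Acta1 and Prx in DKO, the basement membrane list in WT and Pi16 in the interaction, and no other call of these. DKO and WT libraries of a number deviated together for FAP replicates 1 (0.29) but for no other pair (−0.06 to 0.09 in FAP, −0.16 to 0.03 in Misc, −0.05 in SMP), so that block rests on a number alone; it gave 1381, 2317 and 2738 genes. By replicate number, SMP did not pair with the others either (−0.26 to 0.06). By column letters its correlations with them were −0.14 to 0.08 in DKO and 0.05 to 0.15 in WT. Blocking by number within genotype gave 7882 and 8785 genes for FAP against SMP, and 8044 and 8534 for Misc against SMP. It gave 1305 and 1143 for the interactions with SMP. A block by column letters, which pairs FAP with Misc as the numbers do but places SMP differently, moved the FAP to Misc interaction to 737; the cause was not tested. At these depths the simulated recovery of 2-fold changes was 59% in SMP, so genes missed there are not shown to be unchanged.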

Other observations

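The tests of length and of cell-type genes by library were chosen only after the results were seen. The test of genes near Des and Syne1, the assumed targets, was planned before its result.

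Of the genes called in all 3 populations, 133 were higher and 154 lower in DKO in each, against 8.53 and 7.79 for independent lists; without SMP DKO replicate 2 the counts were 91 and 134, with 209 of the 287 genes among them. The lists are not independent, since same-numbered FAP and Misc libraries deviated together. Sex in SMP and the column letters in all 3 populations also go with genotype. How much of the excess comes from these was not measured. Some of the genes stood out after their values were seen. The neuropeptide gene Tac1 rose by 2.26, 2.34 and 3.70 (log2, FAP, Misc and SMP), the interleukin 33 receptor gene Il1rl1 by 1.70, 2.18 and 2.29, the glycosyltransferase Gcnt4 by 2.60, 2.17 and 1.95, the prolyl hydroxylase P4ha3 by 1.91, 1.57 and 2.11, and AI506816 by 5.49, 4.39 and 5.58. The adrenergic receptor Adra1a changed by −1.59, −1.98 and −1.35, the receptor kinase Ret by −1.16, −1.69 and −1.57, the collagen Col9a2 by −1.63, −1.47 and −1.64, and glutamine synthetase (Glul) by −0.85, −0.89 and −0.99. Of the 287, 11 (3.8%), Des itself included, lay within 20 Mb of Des or Syne1, against 309 (2.2%) of the genes tested. The ratio was 1.76 (exact hypergeometric p = 0.05). Both values count Des itself, so they overstate the share of genes that only flank Des or Syne1. The p is therefore not a test of flanking genes alone. If these are the targeted loci, strain alleles that flank them may account for a few of the 287. This ratio lies between the values set for either answer. Genes changed by the knockout itself cannot be told apart from flanking ones here, so most of the 287 stay without a tested explanation.

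The tendon gene Tnmd was at 1980 ± 180 CPM in Misc DKO and 2200 ± 362 in Misc WT, 58 ± 19.7 and 41.2 ± 5.89 in FAP (mean ± SD, n = 4 each), and 126 ± 48.3 and 239 ± 41.7 in SMP (n = 2 each). Longer transcripts had lower fold changes in SMP: Spearman's rho between log2 fold change and transcript length was −0.24 across genes, with medians of 0.26 under 2 kb and −0.16 over 5 kb. It was −0.17 in Misc and −0.08 in FAP, for the 91.9% of tested genes with a length; genes are not independent replicates. Ribosomal Rn45s took 0.9% to 1.33% of counts in the group means, and Hspa1a 0.73% (Misc WT) to 2.43% (SMP WT).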
